A study of Mus musculus with 6 samples.

How the data were processed

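Gene expression was measured on 6 Affymetrix arrays, 2 for each of 3 groups of mouse cells. Per the labels' protocols, the cells were a line of pre-pro-B progenitors that lack Ebf1, kept on OP9 stromal cells with IL-7, FLT3 ligand and stem cell factor at 10 ng per ml each. The groups are the retroviral vectors the cells received. Control cells carried the empty MigR1 vector, EBF1 cells a vector for EBF1, and Pax5 cells a vector for Pax5. Sorted cells gave RNA at 24 hours after transduction. Per the labels' protocols, 50 ng of total RNA was amplified with a NuGEN whole-transcriptome kit (poly(T) and random priming), then fragmented and labelled with biotin. The labels number the arrays 1 and 2 within each group, and nothing says whether these came from separate transductions, so that p-values measure only the spread between these samples, which may be technical.

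Per the submitters' processing notes, the authors used RMA and Partek 6.5. The deposited values are log2 expression values after RMA (background correction, normalization between arrays and summary per probe set). The RMA options, the version of the probe annotation and its genome build are not given in the sources used here, and no coordinates are reported for that reason. A second deposited table repeats the log2 values of the 6 arrays and adds, per the file headers, a p-value and a step-up adjusted p-value for each pair of groups. Per the file headers it also holds the authors' ratios of group means, signed fold changes, and the F statistic (used here as a score to identify the test). The log2 values in both deposited tables were equal for all 28350 probe sets (largest difference 0). The authors' F fell within 1% of a one-way analysis of variance of the 6 values for 99.96% of the probe sets. The median log2 value per array, over all probe sets, was 4.165 and 4.12 for Control 1 and 2, 4.15 and 4.11 for EBF1 1 and 2, and 4.17 and 4.06 for Pax5 1 and 2.

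Gene symbols came from the annotation column of the deposited table. Of the probe sets, 22969 carried 1 symbol, 2285 carried several and 3096 carried none. The annotation text ends at 255 characters in the deposited table, so some probe sets counted as having 1 symbol may carry more. Gene identifiers matched a RefSeq gene table (assembly GRCm38.p6, used for names and gene order only) for 22138 of the probe sets with 1 symbol, and 2532 of these received a newer symbol. Probe sets with several symbols or none stayed out of the gene tests. Where a symbol had several probe sets, the one with the highest mean over the 6 arrays was used. A gene was tested when its value lay above the 30th percentile of the array on at least 2 arrays, which left 15295 genes. RMA values have no detection call here, and the number of arrays limits the precision.

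Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values, in 1 model with a mean for each of the 3 groups, so that all arrays share the estimate of the spread. The model had 3 residual degrees of freedom per gene and 3.18 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 15295 genes, and a gene was called at an adjusted p of 0.05. Every adjusted p for a gene comes from limma, and every SE is that of the limma log2 difference. A gene was called EBF1-selective when it passed both against Control and against Pax5 in the same direction, and Pax5-selective in the mirror way. Shared genes passed against Control in the same direction with both factors, and opposite genes in opposite directions. These classes overlap, because a selective gene may also have changed with the other factor. Because both factors were set against the same Control arrays, 100 draws of unchanged groups sharing those controls were simulated.

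A set of 18 gene lists was fixed before the data were examined, as were the tests, the rule for naming genes and most alternatives. The lists hold 313 distinct genes, of which 30 are in more than 1 list, and neither Ebf1 nor Pax5 is in any. They cover the pre-BCR and BCR complex, early B-lineage genes known as EBF1 targets, genes known as Pax5-activated, genes known as Pax5-repressed, B-lineage transcription factors, T-lineage genes, NK and innate lymphoid genes, myeloid genes, dendritic cell and MHC class II genes, stem and progenitor genes, IL-7 receptor and STAT5 signalling, V(D)J recombination and end joining, cell cycle, interferon response, p53 targets, stress and immediate early genes, stromal (OP9) genes, and erythroid and megakaryocyte genes. Lists were tested with limma's camera at an inter-gene correlation of 0.01, which compares a list with the other genes, adjusted over the 18 lists of a comparison. Camera with an estimated correlation, fry (which tests whether a list's genes move, on balance, one way, without comparing them with other genes) and camera on ranks were run beside it. With an estimated correlation, camera uses the 3 residual degrees of freedom, so a call can end there without correlated members. Early B-lineage genes known as EBF1 targets, for Pax5 against Control, had an estimated correlation of -0.047. Their camera p still went from 3.7e-11 to 0.0057. Counts of list members "adjusted over the list alone" use Benjamini-Hochberg within the list.

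The rule for named genes took Ebf1 and Pax5, the 8 largest rises and 8 largest falls of each comparison among called genes whose arrays did not overlap between groups, up to 4 called members of each list (or, where none passed, the 1 or 2 with the smallest p), 8 genes fixed beforehand (Gata3, Cd79a, Igll1, Id2, Tcf7, Blk and Foxo1 among them), and the 5 largest changes of each selective, shared and opposite class. The text names genes from these 122, and says where a gene outside the rule is named. Plcg2, Dapp1, Lyn, Btk and Rel are outside it and were chosen, as members of small counts, after their values were seen. Of the 8 fixed genes, 1 is not reported here.

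The gene and list tests were checked on simulated data with the spread that limma fitted for each gene over all groups. There were 5 runs of 15295 genes with 200 changed genes each. For EBF1 against Control, 47.0% of the genes changed by 0.5 log2 units, 97.3% of those changed by 1 and 100% of those changed by 2 were called. For Pax5 against Control the shares were 43.6%, 98.5% and 100%. Of unchanged genes, 0.0596% were called in each comparison. A list shifted by 0.3 log2 units was called in 5 of 5 runs of both comparisons, and 1 and 0 of 85 unshifted lists were called. The simulated genes varied independently, and each gene had the same spread in all groups. These runs therefore do not check list calls where members are correlated. Nor do they check gene calls where a group varies more than the others, as Pax5 did. The SD of the difference between its arrays was 0.263, against 0.152 for Control and 0.161 for EBF1. The estimated correlation was 0.39 for the interferon list and 0.18 for the pre-BCR and BCR complex.

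The alternatives were no filter or a filter at the 50th percentile, the mean of a symbol's probe sets, all probe sets tested alone, the 4 arrays of a comparison alone, the replicate number as a block, eBayes with trend and robust options, a repeated quantile normalization, centring on the array median, array weights, a 2-fold minimum, an adjusted p of 0.1, the authors' deposited p-values, and leaving out each array in turn. Naming probe sets by the deposited symbol column, and separate controls for the correlation, were added after seeing the data. With 1 array left in a group, limma assumes that it varies like the other groups.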

Results

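The series set EBF1 beside Pax5, the transcription factors that specify and commit B cells, in progenitors that lack Ebf1. Expression was measured at 24 hours after transduction with an empty vector (Control), an EBF1 vector or a Pax5 vector, on 2 arrays per group. Values are log2 RMA values, and changes are log2 differences of group means with their SE from limma (n = 2 arrays per group). Arrays of a group correlated at r = 0.9979 for Control, 0.9976 for EBF1 and 0.9923 for Pax5 across probe sets, which are not independent replicates. Over the 15295 genes tested, the SD of the difference between the arrays of a group was 0.152 for Control, 0.161 for EBF1 and 0.263 for Pax5.

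The genes carried by the vectors were read first. Pax5 (probe set 10512669, chromosome 4) had a mean of 5.02 ± 0.13 (SD, n = 2) in Control and 11.38 ± 0.06 in Pax5 cells, a log2 change of 6.36 (SE 0.10, adjusted p = 5.1e-06). It lay at 11.42 and 11.33 on the 2 Pax5 arrays. Its signal in Pax5 cells may hold RNA from the vector and from the gene alike, since the position of this probe set is not given in the sources used here. Ebf1 (probe set 10375360, chromosome 11) was 8.87 in Control, 9.92 ± 0.06 in EBF1 cells and 8.89 ± 0.04 in Pax5 cells. It rose by 1.05 with EBF1 (SE 0.08, adjusted p = 0.0023) and changed by 0.02 with Pax5 (adjusted p = 0.88). The position of this probe set relative to the deleted part of the gene is not given in the sources used here, so its Control level does not check the knockout. A second, dimmer Ebf1 probe set moved differently: its log2 change was -0.42 with EBF1 (adjusted p = 0.084) and 1.30 with Pax5 (adjusted p = 0.0043), in limma over all probe sets. With the mean of both probe sets, the Ebf1 change was 0.31 with EBF1 (adjusted p = 0.062) and 0.66 with Pax5 (adjusted p = 0.0069).

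**Figure D1:**
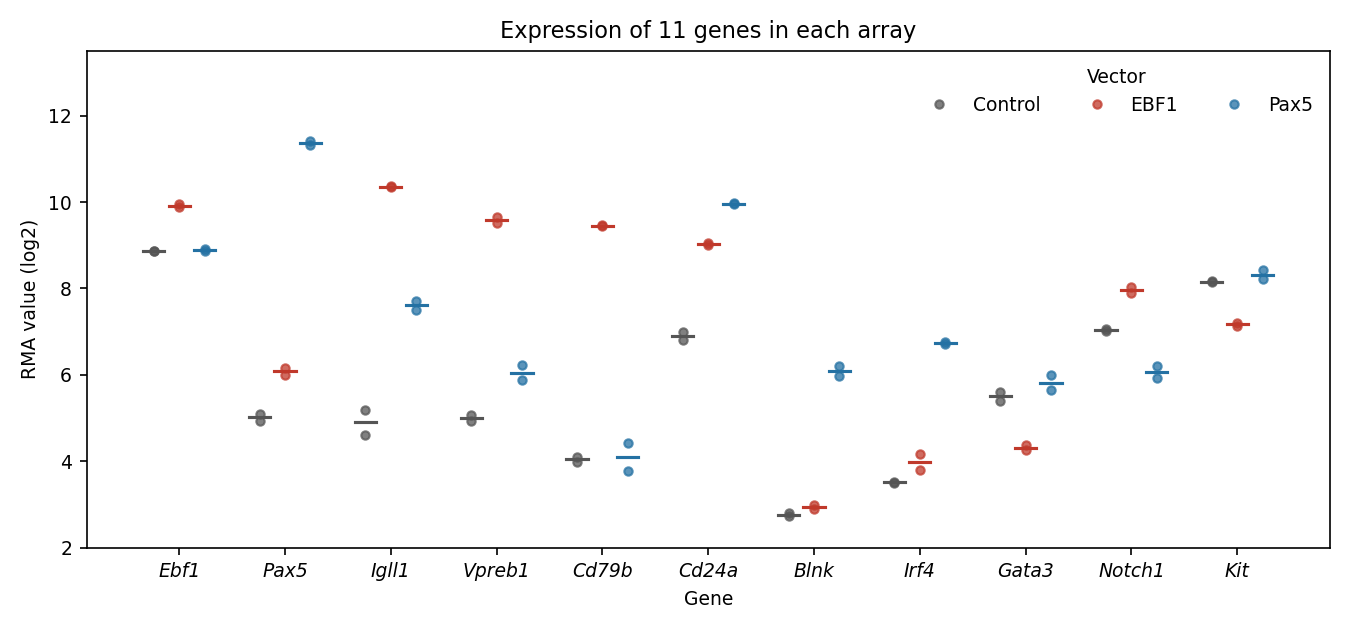
RMA values (log2, vertical axis) of 11 genes (horizontal axis) on each of the 6 arrays, coloured by vector, where points are arrays and short lines are means of the 2 arrays of a group. Igll1 lay at means of 4.91, 10.35 and 7.61 in Control, EBF1 and Pax5 cells, while Cd79b was high in EBF1 cells (9.46) and Blnk in Pax5 cells (6.09).

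Which genes EBF1 changed was asked by setting EBF1 cells against Control. The largest rises were in the surrogate light chain and the receptor complex it joins. Igll1 rose 43.4-fold (log2 change 5.44, SE 0.19, adjusted p = 0.00024; probe set 10438060, chromosome 16). Cd79b, a signalling chain of the B cell receptor, rose 42.6-fold (5.41, SE 0.21, adjusted p = 0.0003; probe set 10392142, chromosome 11). Vpreb1 rose by 4.58 (SE 0.14) and Vpreb2 by 5.01 (SE 0.21), which are uncertain one by one because these paralogs are near-identical. Cd24a, a surface glycoprotein of developing B cells, rose by 2.14 (SE 0.09, adjusted p = 0.0003) and Ly6d, a marker of B-biased lymphoid progenitors, by 2.33 (SE 0.08, adjusted p = 0.00024). Pax5 itself rose by 1.07 (SE 0.10, adjusted p = 0.0043). Among the falls, Dntt, which encodes terminal transferase, changed by -1.75 (SE 0.12, adjusted p = 0.0022), and the chemokine receptor gene Ccr9 by -1.61 (SE 0.12). Gata3, a transcription factor of T and innate lymphoid cells, changed by -1.19 (SE 0.14, adjusted p = 0.0089), and Kit, the stem cell factor receptor, by -0.99 (SE 0.10, adjusted p = 0.0046).

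At an adjusted p of 0.05, 857 genes changed with EBF1, 480 higher and 377 lower, and 150 of them by at least 2-fold (107 higher, 43 lower). The other leading rises were 9330175E14Rik (3.36), Bhlha15, a basic helix-loop-helix transcription factor (3.24), the imprinted noncoding RNA H19 (3.08) and Gzma, a granzyme (3.04). The other leading falls were Rinl (-1.93), 5830411N06Rik (-1.75), Mir340 (-1.64), Igf1 (-1.55), Lyzl1 (-1.54) and Kcne3 (-1.48). Gzma in Control (2.62) and Mir340 in EBF1 cells (2.39) lay below the lower quartiles of these arrays (2.72 to 2.78), as did Rasgrp3 in EBF1 cells (2.52), so the sizes of these changes are lower bounds. Several B-lineage genes did not pass, among them Cd79a (0.07, SE 0.25, adjusted p = 0.92), Blk (0.32, adjusted p = 0.22) and Foxo1 (-0.13, adjusted p = 0.61). Tcf7 (0.33, adjusted p = 0.058) and Id2 (0.01, adjusted p = 0.97), which act in T and innate lymphoid cells, did not pass either.

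Of the 18 tested members of the pre-BCR and BCR complex, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with Plcg2 (0.48) the smallest rise and Dapp1 (-0.59) and Lyn (-0.37) the falls. The list was called higher by camera (adjusted p = 0.0057; adjusted p = 0.376 with an estimated correlation), with a median change of 0.14 and a mean of 1.14. Early B-lineage genes known as EBF1 targets had 5 of 17 members that rose and 0 that fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00062; adjusted p = 0.223 with an estimated correlation). The median change of this list was 0.14 and the mean 1.12. With camera on ranks neither list was called (adjusted p = 0.092 and 0.055). Genes known as Pax5-activated, tested on 17 members, had 3 that rose, Spib (1.29), Cd72 (0.63) and Irf8 (0.46), and Rasgrp3 that fell (-0.77). Adjusted over the list alone the counts were 4 and 1, and the list was not called (adjusted p = 0.126). Among 20 B-lineage transcription factors, Pou2f2 (1.67), Bcl11a (1.38), Spib and Irf8 rose while Runx1 (-0.58) and Rel (-0.50) fell (6 and 3 adjusted over the list alone; adjusted p = 0.261).

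Stem and progenitor genes were called lower (adjusted p = 0.00089; adjusted p = 0.223 with an estimated correlation). Kit and Cd27 (-1.04) fell and 0 of 17 rose, while 8 fell and 2 rose adjusted over the list alone, with a median of -0.23. The T-lineage list held movements both ways, with Hes1 (1.06), Notch1 (0.93) and the adaptor gene Lat (0.74) higher and Gata3 lower among 21 members (4 and 1 adjusted over the list alone; adjusted p = 0.131). Of 14 NK and innate lymphoid genes, Gzma rose and the cytokine receptor genes Il2rb (-0.78) and Il18r1 (-0.78) fell (1 and 4 adjusted over the list alone; adjusted p = 0.131). The mean was 0.01, where the median (-0.07) and the test ran lower. Of 19 myeloid genes, Itgam (-1.06), Adgre1 (-0.72) and Fcgr3 (-0.59) fell and Cebpb rose (0.61), with 2 and 4 adjusted over the list alone (adjusted p = 0.136). Dendritic cell and MHC class II genes had 3 that rose, Ly6d among them, and 3 that fell, including Ccr9 and Siglech (-0.87), of 15 tested (3 and 3 adjusted over the list alone; adjusted p = 0.911). Of 16 genes known as Pax5-repressed, Cd33 (1.05) and Notch1 rose and Ccr2 (-1.44) and Fcgr3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.864).

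Of 19 members of the IL-7 receptor and STAT5 list, Cish (1.06), a feedback inhibitor induced by STAT5, rose with the growth genes Ccnd3 (0.95), Ccnd2 (0.67) and Myc (0.52). Il7r fell (-0.39), and the list was not called (7 and 5 adjusted over the list alone; adjusted p = 0.136). With the mean of its probe sets, Ccnd2 changed by 0.25 (adjusted p = 0.16), and with the replicate number as a block Il7r did not pass (adjusted p = 0.073). The block ended other calls too, which are named with the processing alternatives below. The p53 target list was called higher (adjusted p = 0.043; adjusted p = 0.376 with an estimated correlation). Cdkn1a (0.97) and Phlda3 (0.86) rose, Sesn1 fell (-0.45) and 10 of 13 members did not pass (3 and 1 adjusted over the list alone). That call ended without Control 1 (adjusted p = 0.123), EBF1 1 (0.057) or EBF1 2 (0.052), and on ranks (0.055). The interferon response list was called lower (adjusted p = 0.046; adjusted p = 0.448 with an estimated correlation). Mx2 (-0.53) and Ddx58 (-0.50) fell and Mx1 (0.62) rose, of 15 (1 and 4 adjusted over the list alone). The call ended without Control 2 (adjusted p = 0.184) or EBF1 2 (0.112), and on ranks (0.055). Dntt and the end-joining gene Xrcc6 (-0.56) fell among 15 V(D)J recombination genes (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.136). Of 24 cell cycle genes 0 passed in the main limma test, over all genes or adjusted over the list alone. Camera did not call the list (adjusted p = 0.193), but fry called it higher (adjusted p = 0.0052), with a positive change in 17 members. The smallest p values belonged to Rrm2 (0.35, adjusted p = 0.076) and Bub1 (-0.22, adjusted p = 0.21). With the trend and robust options of eBayes both passed (adjusted p = 0.0031 and 0.039). Asns (0.47) rose among 18 stress genes (2 and 0 adjusted over the list alone; adjusted p = 0.126). Bgn (0.62) rose among 19 stromal genes (1 and 0; adjusted p = 0.136) and Gp9 (1.10) among 8 erythroid and megakaryocyte genes (1 and 0; adjusted p = 0.575). The erythroid median of -0.04 differed in sign from its mean of 0.12 and its test.

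The count of 857 became 109 and 103 without Control 1 and 2, 106 and 123 without EBF1 1 and 2, and 1424 without either Pax5 array. Of the 72 named genes called here, 29 passed whichever array was left out, Igll1, Cd79b, Vpreb1, Cd24a, Ly6d, Dntt and Ccr9 among them, while Pax5, Gata3 and Kit did not.

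Which genes Pax5 changed was asked in the same way. Blnk, the adaptor that links the pre-BCR to its downstream kinases, rose at least 10.0-fold (log2 change 3.32, SE 0.10, adjusted p = 0.00013; probe set 10467508, chromosome 19), from a Control mean of 2.76. The transcription factor gene Irf4 rose 9.3-fold (3.22, SE 0.13, adjusted p = 0.0003), and Cd24a rose 8.36-fold (3.06, SE 0.09, adjusted p = 0.00013). Igll1 rose by 2.70 (SE 0.19, adjusted p = 0.0023). Hbb-bh1, an embryonic beta-like globin gene (probe set 10566268, chromosome 7), rose from 2.33 ± 0.13 to 8.69 ± 0.08 (log2 change 6.36, SE 0.10, adjusted p = 5.1e-06). The Control levels of Blnk and Hbb-bh1 lay near or below the lower quartile of the Control arrays (2.78 and 2.72), so their changes are lower bounds. Dntt fell by 1.27 (SE 0.12, adjusted p = 0.0057), and Notch1 by 0.97 (SE 0.11, adjusted p = 0.01). The cytokine receptor gene Il7r fell by 0.79 (SE 0.07, adjusted p = 0.005) and Flt3, another cytokine receptor gene, by 0.50 (SE 0.08, adjusted p = 0.031).

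In all, 646 genes changed with Pax5, 331 higher and 315 lower, 118 of them by at least 2-fold (94 higher, 24 lower). With the spread of the 4 Control and Pax5 arrays alone, 240 passed (155 higher, 85 lower). The split was 362 higher and 256 lower after a repeated quantile normalization, and 437 and 563 with a filter at the 50th percentile. Other leading rises were the neuropeptide gene Cartpt (3.55), the carboxypeptidase gene Cpn1 (3.22) and Enpep (2.94), an aminopeptidase found on early B cells. Leading falls were LOC100502704 (-1.84), Ctla4 (-1.39), 5830411N06Rik (-1.33), Slc17a8 (-1.32), Ptpn21 (-1.24), Olfr525 (-1.17) and B3galt5 (-1.12). Gata3 changed by 0.32 (SE 0.14, adjusted p = 0.27) and Id2 by -0.43 (SE 0.09, adjusted p = 0.061). Cd79a (0.26, adjusted p = 0.59), Tcf7 (0.09, adjusted p = 0.51), Blk (-0.14, adjusted p = 0.57) and Foxo1 (-0.03, adjusted p = 0.89) did not pass.

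Genes known as Pax5-activated had 7 of 17 members that rose and 0 that fell (9 and 0 adjusted over the list alone), with Blnk, Irf4 and Nedd9 (1.08) among them. The list was called higher (adjusted p = 1.2e-10; adjusted p = 0.102 with an estimated correlation). Of the 17 early B-lineage genes known as EBF1 targets, 8 rose and 0 fell (9 and 0 adjusted over the list alone), led by Blnk, Cd24a, Igll1 and Vpreb3 (1.99). This list was called higher as well (adjusted p = 3.3e-10; adjusted p = 0.102 with an estimated correlation). These lists share genes. Vpreb1 rose by 1.06, but its near-identical paralog Vpreb2 did not pass with Pax5. The Vpreb1 call also ended without at least 1 array, so its rise is uncertain. The pre-BCR and BCR complex had 6 that rose, Vpreb1 and Btk (0.46) among them, and Dapp1 that fell (-0.49), of 18 (7 and 2 adjusted over the list alone). It was called higher (adjusted p = 0.00073; adjusted p = 0.473 with an estimated correlation), and not without Pax5 1 (adjusted p = 0.095) or with camera on ranks (0.052). Irf4, Ets1 (1.44) and Irf8 (0.72) rose and 0 of 20 B-lineage transcription factors fell (8 and 1 adjusted over the list alone; adjusted p = 0.00076; adjusted p = 0.157 with an estimated correlation). Genes known as Pax5-repressed had 4 of 16 that fell, Notch1, Fcer1g (-0.79), Emb (-0.55) and Flt3, and 1 that rose, Ccl3 (0.60), with 3 higher and 7 lower adjusted over the list alone (adjusted p = 0.14). With the mean of its probe sets, Emb changed by -0.27 (adjusted p = 0.14).

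The IL-7 receptor and STAT5 list was called lower (adjusted p = 0.033; adjusted p = 0.473 with an estimated correlation). Il7r, Pim1 (-0.54) and Ccnd2 (-0.39) fell, and the survival gene Bcl2l1 (0.90) and Ccnd3 (0.46) rose, of 19 (2 and 7 adjusted over the list alone). After a repeated quantile normalization neither Pim1 (-0.49, adjusted p = 0.057) nor Ccnd2 (-0.33, adjusted p = 0.074) passed, and with the mean of its probe sets Ccnd2 changed by -0.24 (adjusted p = 0.18). The call of the list as lower ended after the quantile normalization. That call ended without Control 2 (adjusted p = 0.068), Pax5 1 (0.095) or Pax5 2 (0.069). The remaining lists were not called. NK and innate lymphoid genes had 3 that fell, Tox (-0.84), Fcer1g and Il18r1 (-0.67), and 0 that rose (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.203). Among myeloid genes Mpo (-1.03), a granule enzyme, and Fcer1g fell (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.914), with a mean of 0.05 against a median of -0.01 and a test that ran lower. Dendritic cell and MHC class II genes moved both ways, with Zeb2 (1.13), Itgax (0.75) and Irf8 higher and Siglech (-1.07) and Ly6d (-0.97) lower (6 and 6 adjusted over the list alone; adjusted p = 0.599). Cd7 (0.69) rose and Notch1 fell in the T-lineage list (2 and 1 adjusted over the list alone; adjusted p = 0.369). Hhex (0.71) rose and Flt3 fell among stem and progenitor genes (1 and 4 adjusted over the list alone; adjusted p = 0.853).

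Dntt and Rag1 (-0.63), a recombinase gene, fell among V(D)J recombination genes (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.914); the median and mean of this list were below 0 and its test ran higher. Mx2 (1.30) rose and Ifih1 (-0.77) fell in the interferon list (2 and 2 adjusted over the list alone; adjusted p = 0.519). Among p53 targets Trp53inp1 (0.49) and Cdkn1a (0.45) rose and Phlda3 (-0.73) fell (2 and 2 adjusted over the list alone; adjusted p = 0.914). The list's median was 0.11 higher on Pax5 2 than on Pax5 1, at the 99.3 percentile of random lists matched on mean expression. The median of the pre-BCR and BCR complex was lower on Pax5 2 (-0.16, at the 1.84 percentile). These are the highest and lowest percentiles of the 18 lists, not adjusted for that number, and the comparison was chosen after the results were seen. The random lists took no account of correlation between members, estimated at 0.18 for the pre-BCR and BCR complex. Of 24 cell cycle genes 0 passed in the main limma test, over all genes or adjusted over the list alone (adjusted p = 0.7 for the list, whose mean of -0.01 differed in sign from its median and test). Mcm3 (-0.40, adjusted p = 0.073) and Mcm2 (-0.25, adjusted p = 0.15) had the smallest p values. With the trend and robust options of eBayes both passed (adjusted p = 0.0041 and 0.024). So did Mcm5 (-0.36, adjusted p = 0.032) and, as a rise, Rrm2 (0.27, adjusted p = 0.016). Hspa5 (-0.54) fell among stress genes (1 and 3 adjusted over the list alone; adjusted p = 0.853). Of 19 stromal genes 0 passed over all genes (0 higher and 2 lower adjusted over the list alone; adjusted p = 0.914). Gp9 (-0.53) fell among erythroid and megakaryocyte genes (0 and 1 adjusted over the list alone; adjusted p = 0.794).

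The count of 646 became 60 and 62 without Control 1 and 2 (52 higher and 8 lower without Control 1), 240 without either EBF1 array, 2407 without Pax5 1 (864 higher and 1543 lower), and 464 without Pax5 2 (397 of these among the 646). Of the 62 named genes called here, 18 passed whichever array was left out (Blnk, Irf4, Cd24a, Igll1, Hbb-bh1 and Pax5 among them), while the calls of Dntt, Notch1, Il7r and Flt3 ended without at least 1 array.

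**Figure D2:**
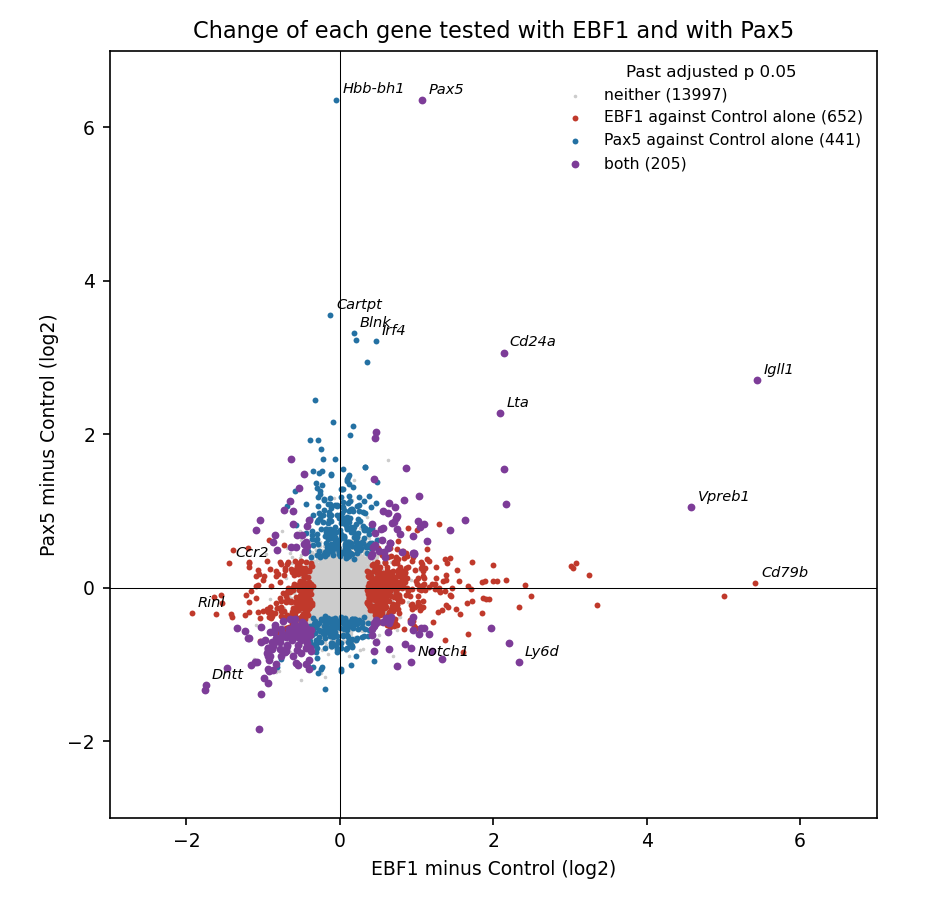
Log2 change with EBF1 (horizontal axis) against log2 change with Pax5 (vertical axis), both against Control, for each of the 15295 genes tested, coloured by which of these tests passed an adjusted p of 0.05. Igll1, Cd24a and Lta lay high on both axes, Cd79b on the EBF1 axis and Blnk and Hbb-bh1 on the Pax5 axis.

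The comparison that the series names, EBF1 against Pax5, found the surrogate light chain and Cd79b on the EBF1 side and Blnk and Irf4 on the Pax5 side. Cd79b was higher in EBF1 cells by 5.36 (SE 0.21, adjusted p = 0.0002), Vpreb1 by 3.53 (SE 0.14) and Ly6d by 3.30 (SE 0.08, adjusted p = 4.5e-05). Igll1 was higher by 2.74 (SE 0.19, adjusted p = 0.00088) and Notch1 by 1.90 (SE 0.11, adjusted p = 0.00064). Pax5 cells were higher in Blnk (EBF1 minus Pax5 -3.14, SE 0.10, adjusted p = 0.00011) and Irf4 (-2.75, SE 0.13). They were also higher in Gata3 (-1.51, SE 0.14, adjusted p = 0.0022) and Kit (-1.15, SE 0.10, adjusted p = 0.0016). The genes of the vectors differed by 1.02 for Ebf1 (adjusted p = 0.0011; with the mean of both probe sets -0.35, adjusted p = 0.025) and -5.29 for Pax5 (adjusted p = 1.6e-05).

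Altogether 2128 genes differed between the factors, 1332 higher with EBF1 and 796 higher with Pax5, and 274 by at least 2-fold (135 and 139). After a repeated quantile normalization the split was 1067 and 941. Further genes high with EBF1 were Vpreb2 (5.12), 9330175E14Rik (3.58), Bhlha15 (3.08), Cracdl (2.92) and Gzma (2.78). Further genes high with Pax5 were Hbb-bh1 (-6.41), Cartpt (-3.68), Cpn1 (-3.01), Pgf (-2.77) and Enpep (-2.59). Hbb-bh1 and Blnk were dim in EBF1 cells as well (2.28 and 2.95), and Gzma in Pax5 cells (2.88). Id2 was higher with EBF1 (0.44, adjusted p = 0.028). Blk (0.46, adjusted p = 0.059), Tcf7 (0.24, adjusted p = 0.084), Cd79a (-0.19, adjusted p = 0.66) and Foxo1 (-0.10, adjusted p = 0.6) did not pass.

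Genes known as Pax5-activated were called lower in EBF1 than in Pax5 cells (adjusted p = 1.5e-05; adjusted p = 0.47 with an estimated correlation). Blnk, Irf4 and Rasgrp3 (-1.07) were among 7 of 17 on the Pax5 side, and 0 were on the EBF1 side (7 and 0 adjusted over the list alone). The size of the Rasgrp3 difference is a lower bound, because the gene was dim in EBF1 cells. The IL-7 receptor and STAT5 list was called higher with EBF1 (adjusted p = 0.024; adjusted p = 0.47 with an estimated correlation). Of 19 members 9 were higher, among them Cish (1.33), Pim2 (1.08), Ccnd2 (1.06) and Pim1 (0.87), and Bcl2l1 was lower (-0.66). Adjusted over the list alone the counts were 10 and 2, and the call ended without Pax5 1 (adjusted p = 0.071) and with camera on ranks (0.066). Members of the pre-BCR and BCR complex lay on both sides, 6 higher with EBF1 and 5 with Pax5 (8 and 5 adjusted over the list alone; adjusted p = 0.908). The median of -0.10 differed in sign from the mean of 0.60 and the test. Early B-lineage genes known as EBF1 targets had 3 higher with EBF1, Cd79b, Vpreb1 and Igll1, and 7 higher with Pax5 (4 and 7 adjusted over the list alone; adjusted p = 0.133), among them Blnk and Vpreb3 (-1.85). The mean of 0.18 differed in sign from the median of -0.19 and the test.

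No other list was called. Genes known as Pax5-repressed had 6 higher with EBF1, such as Notch1, Cd33 (1.34), Ly6a (0.79) and Fcer1g (0.75), and Ccr2 (-1.77) lower (7 and 4 adjusted over the list alone; adjusted p = 0.252). Pou2f2 (1.65) and Bcl11a (1.00) were on the EBF1 side and Irf4 and Ets1 (-1.34) on the Pax5 side of the B-lineage transcription factors (3 and 6 over all genes and adjusted over the list alone; adjusted p = 0.149). The median of 0.01 differed in sign from the mean of -0.16 and the test. T-lineage genes split into 3 higher with EBF1, Notch1, Lat (0.84) and Hes1, and 2 lower, Gata3 and Cd7 (-1.06), with 6 and 5 adjusted over the list alone (adjusted p = 0.657). Gzma was higher with EBF1 and Klrb1c (-1.41) and Il2rb (-0.65) with Pax5 in the NK and innate lymphoid list (4 and 2 in both counts, over all genes and adjusted over the list alone; adjusted p = 0.897). Among myeloid genes Mpo (0.68) and Fcer1g were higher with EBF1, and Itgam (-1.09) and Adgre1 (-0.89) with Pax5 (3 and 2, or 4 and 4 adjusted over the list alone; adjusted p = 0.468). Ly6d was higher with EBF1 and Zeb2 (-1.77), Ccr9 (-1.27) and Itgax (-0.74) with Pax5 among dendritic cell and MHC class II genes (3 and 4, or 6 and 6 adjusted over the list alone; adjusted p = 0.417).

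Kit, Hhex (-0.999) and Cd34 (-0.44) were higher with Pax5 and Ly6a with EBF1 among stem and progenitor genes (1 and 3 in both counts, over all genes and adjusted over the list alone; adjusted p = 0.0862; without Pax5 2, 0.048). Rag1 (1.00) was higher with EBF1 and Xrcc6 (-0.84) and Rag2 (-0.65) with Pax5 (1 and 2, or 1 and 4 adjusted over the list alone; adjusted p = 0.187). Mx2 (-1.83) and Zbp1 (-0.46) were higher with Pax5 and Mx1 (0.57) with EBF1 in the interferon list (1 and 2, or 1 and 5 adjusted over the list alone; adjusted p = 0.0843; without Pax5 2, 0.006). Phlda3 (1.59), Sesn2 (0.85) and Cdkn1a (0.51) were higher with EBF1 among p53 targets (3 and 2, or 4 and 2 adjusted over the list alone; adjusted p = 0.149; without Pax5 2, 0.047). Nr4a1 (0.84), Trib3 (0.76), Hspa5 (0.61) and Asns (0.51) were higher with EBF1 among stress genes (4 and 0, or 6 and 0 adjusted over the list alone; adjusted p = 0.2). Acta2 (0.68), Timp1 (0.47) and Fn1 (0.41) were higher with EBF1 among stromal genes (3 and 0, or 4 and 0 adjusted over the list alone; adjusted p = 0.413). So was Gp9 (1.63) among erythroid and megakaryocyte genes (1 and 0 in both counts; adjusted p = 0.584). Among cell cycle genes, Mcm5 (0.51) and Mcm3 (0.40) were higher and Bub1 (-0.35) lower with EBF1 (2 and 1 in both counts; adjusted p = 0.632). After a repeated quantile normalization Mcm5, Mcm3 and Fn1 did not pass (adjusted p = 0.053, 0.058 and 0.094).

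The count of 2128 became 1093 without either Control array, 410 and 474 without EBF1 1 and 2 (198 higher and 212 lower without EBF1 1), 3884 without Pax5 1, and 1786 without Pax5 2 (1499 of these among the 2128). Of the 98 named genes called here, 62 passed whichever array was left out, Cd79b, Vpreb1, Ly6d, Igll1, Notch1, Blnk, Irf4, Gata3 and Kit among them.

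**Figure D3:**
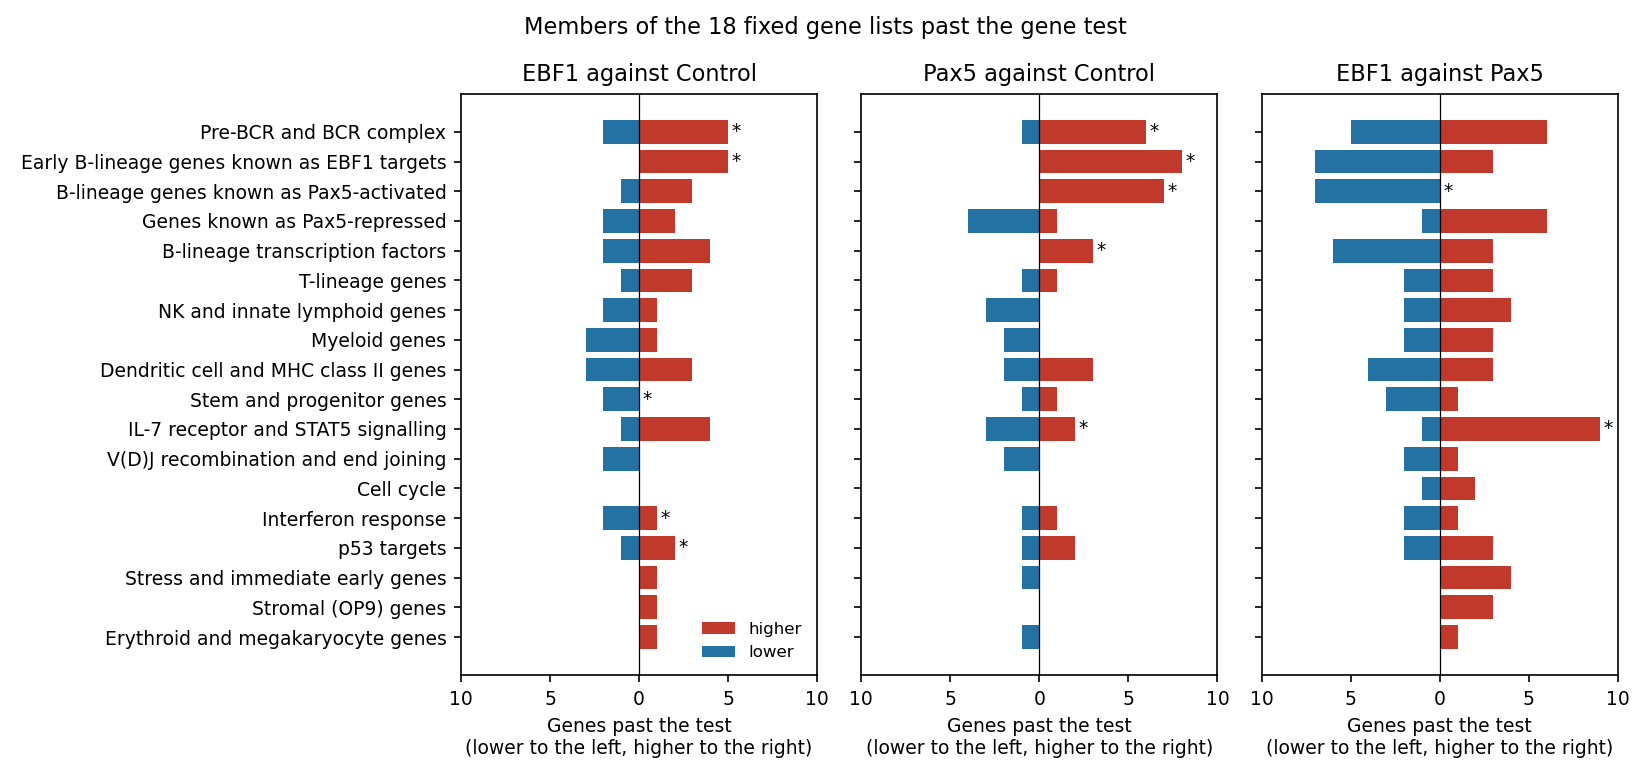
Members of each of the 18 fixed lists past an adjusted p of 0.05 (horizontal axis, number of genes, with higher to the right and lower to the left) in each of the 3 comparisons, where an asterisk marks a list called by camera at a correlation of 0.01. Among genes known as Pax5-activated, 7 rose with Pax5 and 0 fell. None of the calls held with an estimated correlation, where camera has 3 degrees of freedom.

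Sorted by both tests, 382 genes were EBF1-selective and higher and 191 EBF1-selective and lower, and 260 were Pax5-selective and higher and 172 Pax5-selective and lower. The EBF1-selective genes were led by Cd79b, Vpreb2, Igll1, Vpreb1 and 9330175E14Rik upwards and by Rinl, Pstpip2 (-1.39 against Control), Ccr2, Mir340 and Igf1 downwards, and they include Ebf1 itself. The Pax5-selective genes were led by Hbb-bh1, Pax5 (the gene of the vector), Cartpt, Blnk and Cpn1 upwards and by Ly6d, Cracdl, Myl4, Parvb and Notch1 downwards. Ly6d, Cracdl, Myl4, Parvb and Notch1 also rose with EBF1, so each was EBF1-selective and opposite too. Genes that rose with both numbered 49, among them Igll1, Vpreb1, Cd24a, Lta (2.09 with EBF1 and 2.27 with Pax5) and Pax5, the gene that the Pax5 vector carries. The place of Vpreb1 among them is uncertain, because its near-identical paralog Vpreb2 passed against Control with EBF1 only. Genes that fell with both numbered 101, led by 5830411N06Rik, Dntt, LOC100502704, Kcne3 and Ctla4. Lists drawn independently would share 10.4 and 7.76 genes, which takes no account of the shared Control arrays. Of the 150 shared genes, 36 also differed between the factors, Igll1 and Cd24a among them.

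Opposite changes were seen in 55 genes. The 31 that rose with EBF1 and fell with Pax5 were led by Ly6d, Cracdl (2.20 and -0.72), Parvb (1.98 and -0.52), Myl4 (1.33 and -0.93) and Ets2 (1.21 and -0.83). The 24 that fell with EBF1 and rose with Pax5 were led by Ptgr1 (-0.64 and 1.68), Mylip (-0.47 and 1.48), Gm10002 (-1.04 and 0.89), Tigit (-1.09 and 0.76) and Mx2. Independent lists would share 9.89 and 8.16. The 55 became 0 without either Control array, 4 without either EBF1 array, and 166 and 53 without Pax5 1 and 2, and the 150 shared genes became 9 and 8, 17 and 16, and 289 and 139 in the same order. Across the 15295 genes, which are not independent replicates, the changes with EBF1 and with Pax5 correlated at r = 0.178 (Spearman's rho 0.167). Simulated groups without an effect gave r = 0.50 because they share the Control arrays. The covariance was 0.0137 against 0.0074 in the simulation, a difference of 0.0063. The simulated Control arrays had the spread shared by all groups, which the Pax5 arrays raise, so 0.0074 is likely too high and the difference too small. With a separate Control array for each factor, r was 0.0847 and 0.106 and the covariance 0.00707 and 0.00871.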

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

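Values chosen after the data were seen, because they lay above or below the Control arrays, are given here. The probe sets with several symbols and the dimmer Ebf1 probe set were outside the gene tests. Hbb-bh1, Hbb-y and the brighter Ebf1 probe set were in the gene tests, which were planned. Apart from Hbb-bh1 and Ebf1, the probe sets of this part are outside the rule for named genes. The tests of explanations in this part were chosen after the results were seen. Over all probe sets, limma called 42 probe sets with several symbols and 19 without a symbol for EBF1 against Control, and 43 and 15 for Pax5 against Control. With EBF1, the probe set whose symbols begin with Tubb3 changed by 3.43 (from 4.38 to 7.81, adjusted p = 0.0052). The probe set that begins with Eps8l2 changed by 2.87 (from 3.92 to 6.79, adjusted p = 0.0052), and the one that begins with 4933402N22Rik by -2.33 (from 7.18 to 4.85, adjusted p = 0.00096). With Pax5, the probe set that begins with Kcnmb4 changed by 2.14 (from 3.33 to 5.47, adjusted p = 0.0011).

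Several beta-globin probe sets were higher with Pax5, namely Hbb-bh1 (6.36), those that begin with Hbb-b1 (2.51, adjusted p = 0.00064) and Hbb-b2 (2.49, adjusted p = 0.00092), which are near-identical, and Hbb-y (1.34, adjusted p = 0.0095), while Hbb-bh2 (0.38, adjusted p = 0.45) and the alpha-globin probe sets of Hba-a1 (1.62, adjusted p = 0.17), Hba-a2 (1.80, adjusted p = 0.15), Hba-ps4 (-0.03) and Hba-x (-0.35) did not pass. Signal passed to Hbb-bh1 from another globin probe set is argued against by its gap of 3.86 (SE 0.13) over the largest other globin change. Erythroid cells that came through the sort stay open, since the 13 genes tested (the non-globin erythroid and megakaryocyte list and Hba-x) had a median change of -0.014 (SE 0.09) but 12 of them lay below the median of Control values, where a small share of cells could go unseen. The adult alpha-globin probe sets lay above Control on both Pax5 arrays and higher on Pax5 2, the array that stood apart. Hba-a1 lay at 6.02 and 7.38 against a Control mean of 5.08, and Hba-a2 at 6.04 and 7.47 against 4.95. Both also lay above Control on the EBF1 arrays (Hba-a1 at 5.46 and 5.76, Hba-a2 at 5.50 and 5.74). On the Pax5 arrays Hbb-b1 lay at 10.47 and 10.50 and Hbb-bh1 at 8.63 and 8.75, so the alpha- and beta-globins did not move together between these arrays. Hbb-b1 and Hbb-b2 were bright in Control already (means of 7.98 and 7.86). A change of the beta-globin genes in the Pax5 cells themselves is a hypothesis that these arrays leave untested.

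The 2 Ebf1 probe sets moved apart. The dimmer one, outside the gene tests because the brighter one was used, changed by 1.30 with Pax5 (SE 0.08) and by -0.42 with EBF1, where the brighter one changed by 0.02 and 1.05. Noise between arrays is argued against, since the probe sets differed by 10.9 standard errors with Pax5. The dimmer one moved by 15.4 standard errors in the Pax5 cells, which shows only that it moved. Those cells did not receive the EBF1 vector, so by design RNA from that vector could not be the cause there. Whether that RNA raised the brighter one in EBF1 cells cannot be told from these values. An even rise of the whole Ebf1 transcript with Pax5 is argued against by the brighter probe set, whose change minus 50% of the dimmer one's was -0.63 (SE 0.09). A change in RNA from a part of the Ebf1 locus that only the dimmer probe set reads, in a line whose Ebf1 gene is disrupted, may be involved, with the position of either probe set not given in the sources used here.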

How the results depend on the processing

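Separate controls and the naming of probe sets by the deposited symbol column were chosen after seeing the data; the other alternatives were planned. Counts below are for EBF1 against Control (857), Pax5 against Control (646) and EBF1 against Pax5 (2128), in this order, and the cause of a shift was not tested unless the alternative's own construction gives it. Without a filter, with the mean of a symbol's probe sets, with all probe sets tested alone, with repeated quantile normalization, with centring and with the deposited symbol column, each count stayed within 1.5 times. A filter at the 50th percentile, which tests fewer genes, gave 1324 and 1000. Trend and robust options gave 1786, 1643 (615 higher, 1028 lower) and 3369. Array weights gave 1855 for EBF1 against Control. The 4 arrays of a comparison alone gave 1424, 240 and 1093, where each spread comes from those groups only. A 2-fold minimum gave 150, 118 and 274, and an adjusted p of 0.1 gave 1461, 1132 and 3347. The authors' deposited p-values, adjusted over the same genes, gave 197, 100 and 712 (166, 82 and 632 of these among the calls here), and the step-up values in the authors' deposited table were under 0.05 for 6, 20 and 449 of all probe sets. Leaving out 1 array gave 103 to 1424, 60 to 2407 and 410 to 3884.

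Same-numbered arrays showed no shared deviation across genes: their deviations from the group means correlated at 0.009, 0.007 and -0.012. This cannot tell whether they came from one transduction or batch. With the replicate number as a block, 565 and 412 genes passed against Control, 280 were Pax5-selective, 91 shared and 20 opposite, and no list changed its call. Named genes whose call with EBF1 ended were Asns, Cd72, Ddx58, Fcgr3, Il7r, Irf8, Mx2, Mylip and Sesn1. For Pax5 against Control they were Ccl3, Ccnd2, Ccnd3, Cd7, Cdkn1a, Emb, Flt3, Gm10002, Gp9, Hspa5, Ifih1, Pim1 and Trp53inp1. Between the factors they were 5830411N06Rik, Bub1, Emb, Fn1, Mcm3 and Mcm5.

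For gene lists (5, 5 and 2 called), an estimated correlation (with 3 degrees of freedom) gave 0, 0 and 0, and fry 10, 9 and 12. Camera on ranks gave 1 for EBF1 against Control (the stem and progenitor list) and 1 for EBF1 against Pax5 (the Pax5-activated list). No filter gave 3 for EBF1 against Control, and repeated quantile normalization gave 3, 4 and 1. The interferon and p53 lists with EBF1 were lost in both cases. Quantile normalization also lost the IL-7 receptor and STAT5 list for Pax5 against Control and for EBF1 against Pax5. Leaving out 1 array gave 3 to 6, 3 to 5 and 1 to 5 lists.

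The filter at the 50th percentile gave 929 EBF1-selective, 678 Pax5-selective, 247 shared and 105 opposite genes (main counts 573, 432, 150 and 55), and no filter gave 95 shared and 27 opposite. Leaving out 1 array gave 79 to 867, 51 to 1766 (641 higher and 1125 lower without Pax5 1, against 260 and 172), 8 to 289 and 0 to 166. The correlation of the changes was 0.0847 and 0.106 with separate controls, and lay between 0.148 and 0.236 when 1 array was left out.

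For the 122 named genes, over 3 comparisons and 10 alternatives each, 3113 values kept direction and side of the threshold, 455 lost the call, 91 gained it and 1 reversed. Of those lost, 416 came from leaving out 1 array, 28 from the replicate block, 6 from quantile normalization and 5 from the mean of probe sets. The reversal was Ebf1 for EBF1 against Pax5, at -0.35 (adjusted p = 0.025) with the mean of its probe sets, because its 2 probe sets move apart. No detection call limits dim genes here, so changes of genes near the floor are less certain.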

Other observations

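The tests of the Pax5 arrays in this part were chosen after the results were seen, while the gene tests of Il7r, Flt3 and Kit were planned. The Pax5 arrays differed from each other more than the arrays of the other groups: 1077 genes differed by over 0.5 log2 units between them, against 115 for Control and 127 for EBF1, and limma's array weights were 0.49 for the Pax5 arrays against 1.55 and 1.31. A wrong label for Pax5 2 is argued against by its Pax5 level, 6.32 above the Control mean. Cells of another type as the whole cause stay open: 67.4% of the 1077 genes were lower on Pax5 2, but 66.1% of the 115 were lower on Control 2 as well, and other cells that passed the sort would carry the vector and leave the Pax5 level high. A share of stromal cells could not be settled: the stromal list's median difference lay at the 95.5 percentile of matched lists, short of the bound set for it, and the sort would remove cells without the vector. Pax5 2 was the array that stood apart, since it lay farther from each of the 4 Control and EBF1 arrays (SD of the difference over all probe sets 0.357 to 0.403) than Pax5 1 did (0.250 to 0.317); the cause stays open, because the slope of 1.01 of its changes on those of Pax5 1 rests on genes called for being alike on both, and a difference in RNA quality or amplification was not tested.

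Il7r, Flt3 and Kit encode receptors for the cytokines in which the line was kept, and were picked as a group after their values were seen. The levels of Il7r were 9.84 in Control, 9.44 with EBF1 and 9.05 with Pax5, those of Flt3 10.04, 9.72 and 9.54, and those of Kit 8.16, 7.17 and 8.32. Il7r fell with both factors (-0.39 and -0.79), Flt3 fell with Pax5 (-0.50) and Kit with EBF1 (-0.99). Flt3 did not pass with EBF1 (-0.33, adjusted p = 0.09) nor Kit with Pax5 (0.16, adjusted p = 0.41). The Il7r call with EBF1 ended without any 1 of the Control and EBF1 arrays (adjusted p up to 0.254), and Kit differed between the factors by -1.15.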
